A study of Mus musculus with 12 samples.

How the data were processed

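Blood from wild-type mice with a combined burn and tendon-cutting injury (burn/tenotomy) was enriched on a microfluidic chip called the iChip, and RNA of the enriched cells was sequenced as total RNA libraries, per the labels' protocols. The labels describe the material as circulating mesenchymal progenitor cells (cMPCs) together with blood cells. The series title names a signature of heterotopic ossification (HO), the formation of bone in soft tissue. The 12 libraries fall into 3 time groups of 4, taken 6 h, 1 day and 7 days after injury and called 6h, Day1 and Day7. Groups and replicate numbers came from the sample titles. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be partly technical. An uninjured group was not analysed here.

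The deposited table holds a signal per gene, named CPM by the authors, for 37583 genes. STAR 2.7.10, HTSeq 2.0.1 and the genome build mm9 are listed in the submitters' processing notes. The annotation and the step that set the scale are not given in the sources used here. The deposited columns sum to between 351981 and 5611150, so they are not plain CPM, which would sum to the same total in each. Each column consists of whole multiples of the value of 1 read (0.0314 to 0.617), and 100% of values came out whole within 0.001 reads. The recovered totals ran from 5098395 to 12379041 reads per library. The value of 1 read sets the effective library size behind each column, and its ratio to the read total equalled a recomputed TMM factor from edgeR times 0.941 in all 12 libraries. The values are called deposited values below and are reads scaled to this effective library size. The reference at hand is another build than mm9, so only gene names were taken from it (32860 of the IDs matched) and no positions are given.

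The main test was limma 3.58.1 in R 4.3.3 with a trended variance on log2(value + 1), fitted to all 12 libraries with the time group as the sole factor. Genes with a deposited value of at least 1 in at least 4 libraries were tested, 11211 in all, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. A moderated F test asked for any change among the 3 times. Of 32 gene lists fixed before the data were examined, 29 had at least 5 tested members and were tested in each comparison with limma's camera at a preset correlation of 0.01 (87 tests), and again with an estimated correlation. Of the lists too short to test, the sex-linked and the eosinophil, basophil and mast cell lists each had 3 tested members, and none of the 13 mitochondrially encoded genes was in the table. For a list that passed, member counts adjusted over the list alone are given beside those over all genes.

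The genes named were chosen by a rule fixed with the design. It takes up to 8 genes with the largest rise and 8 with the largest fall among changed genes whose groups do not overlap and whose mean is at least 10 in the higher group. It adds up to 4 members of each list with at least 3 changed members, and always the 3 most abundant tested members of the mesenchymal, matrix, chondrogenic and osteogenic lists. Folds against a group with 0 reads are lower bounds from a floor of 3 reads over the group. Ratios with 1 to 3 reads in a group carry exact 95% intervals, which, like the floors and the binomial intervals, cover counting error only. Reads of genes with near-identical copies, such as the haemoglobin genes or Hspa1a and Hspa1b, may be split between the copies, so these genes are uncertain.

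Alternatives fixed at the same time were pseudocounts of 0.25 and 4, no filter, a mean of at least 10, TMM and median-of-ratios scaling, scaling to reads outside haemoglobin, array weights, fits of 2 groups, the replicate number as a block, each library left out, and the count tests of edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Added after seeing the data were scaling to all reads, a term for reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d or Uty, and leaving out the 2 libraries with the fewest genes detected. Lists of mesothelial markers and of hepatocyte genes outside the acute phase were also added after seeing the data. Fits were tested on simulated counts with the real means, dispersions and library sizes and 200 of 11211 genes changed. The changed genes were drawn from those with a mean of at least 10, and genes were simulated independently of each other. Recovery of lower genes and false calls among correlated genes were therefore not measured. For Day1 versus 6h, 15 of 100 genes changed 8-fold and 65 of 100 changed 64-fold were recovered, with 10 false calls. For Day7 versus Day1 these were 16 and 63, with 7 false calls, and for Day7 versus 6h 13 and 73, with 8 false calls.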

Results

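Gene expression was measured by total RNA sequencing in iChip-enriched blood of mice at 3 times after burn/tenotomy, with 4 libraries per time. The series asks whether a signature of circulating mesenchymal progenitors can be read in such blood. Haemoglobin genes took 16.1% (Day1 replicate 2) to 70.3% (6h replicate 3) of the reads of a library. Genes with at least 1 read numbered 10319 ± 1853 (SD, n = 4) at 6h, 14318 ± 1725 (SD, n = 4) at Day1 and 10854 ± 2407 (SD, n = 4) at Day7. The fewest were found in 6h replicate 1 (7631) and Day7 replicate 3 (7635). Library totals averaged 7232960 reads at 6h, 8389480 at Day1 and 9326930 at Day7. Replicates were unlike each other. Across tested genes, which are not independent, log2 values of 2 libraries of a group correlated with r of 0.46 to 0.70 at 6h, 0.63 to 0.81 at Day1 and 0.59 to 0.81 at Day7. Libraries of different groups correlated at 0.39 to 0.74. 6h replicate 4 correlated at 0.52 to 0.60 with other 6h libraries. With Day7 replicates 1 to 4 its r was 0.68, 0.74, 0.57 and 0.68. 6h replicate 3 reached 0.74 with Day1 replicate 2. Reads of Y-linked genes were present in 6h replicates 3 and 4 (76 in each) and in Day1 replicates 2, 3 and 4 (603, 422 and 853). The other 7 libraries, the whole Day7 group among them, had 0. Time and Y-linked status are therefore unevenly mixed.

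From 6h to Day1, 7 of 16 tested liver acute-phase transcripts rose (15 adjusted over the list alone) and 0 fell. Fgg, a fibrinogen chain, rose from 0.135 ± 0.270 (SD, n = 4) to 236 ± 57.6 (SD, n = 4), and Hp, haptoglobin, rose from 28.0 ± 38.1 to 892 ± 471 (SD, n = 4). Ambp, the precursor of alpha-1-microglobulin and bikunin, had 0 reads at 6h and 10724 at Day1, over pooled reads at least 1307-fold higher (1153-fold for the means, 551-fold without 6h replicate 4). F2, prothrombin, had 0 reads at 6h and was over pooled reads at least 1459-fold higher at Day1 (1258-fold for the means, 614-fold without 6h replicate 4).

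In all, 19 of 11211 genes changed between 6h and Day1 in limma, each higher at Day1. Log2 fold changes were 7.70 for Fgg (SE 1.09, limma adjusted p = 0.0013), 7.34 for Fga, 7.07 for Hpx (hemopexin), 6.58 for Fgb, 6.42 for Alb (albumin), 6.30 for Kng1 (kininogen) and 5.79 for Hp. These genes were higher in all 4 Day1 libraries than in any 6h library. The liver list had a median log2 fold change of 5.21, or 6.14 with its 3 members at 0 reads set to their bounds, against 0.52 over all genes (camera adjusted p = 1.37e-22; adjusted p = 0.437 with an estimated correlation). Hepatocyte genes outside the acute phase, a list added after seeing the data, had a median of 3.37 (quartiles 2.14 and 4.13). Of its 22 members 1 rose over all genes and 15 adjusted over the list alone (camera adjusted p = 1.27e-12; adjusted p = 0.194 with an estimated correlation).

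The other 4 of 5 lists that passed camera between 6h and Day1 had 0 changed members each, and 0 adjusted over the list alone. Collagens and matrix proteins were higher (median 1.73, adjusted p = 0.00151; adjusted p = 0.693 with an estimated correlation), a call lost without 6h replicate 2 (adjusted p = 0.185), with a term for Y-linked reads (median 1.12, adjusted p = 0.057) and with no filter (adjusted p = 0.0758). Erythroid genes were lower (median -1.32, adjusted p = 1.38e-08; adjusted p = 0.522 with an estimated correlation). Their median was -0.64 when scaled to reads outside haemoglobin and -0.15 when scaled to all reads, against 1.44 and 1.57 over all genes. T cell markers were lower (median -0.32, adjusted p = 0.0427; adjusted p = 0.728 with an estimated correlation). That call was lost without Day1 replicate 2 (adjusted p = 0.182) or Day1 replicate 4 (adjusted p = 0.0542), and the median turned to 0.97 without 6h replicate 1 (adjusted p = 0.537), whose mean log2 level for this list was 5.10 against 0.71 to 1.67 in the other 6h libraries. The T cell median was also above 0 when scaled to reads outside haemoglobin (0.66) and to all reads (0.47), below the medians of all genes there. It was above 0 and the call was lost with array weights (0.67, adjusted p = 0.667), a pseudocount of 0.25 (0.26, adjusted p = 0.132) and a term for Y-linked reads (0.11, adjusted p = 0.465). TMM and median-of-ratios scaling also ended the call (adjusted p = 0.0519 and 0.0667). Proliferation genes were called lower (adjusted p = 0.0133; adjusted p = 0.728 with an estimated correlation) although their median was 0.03 and their mean -0.19. Their call was lost without 6h replicate 1, 2 or 3 (adjusted p = 0.151, 0.067 and 0.097) or Day1 replicate 2 or 4 (adjusted p = 0.134 and 0.155), and with a term for Y-linked reads (adjusted p = 0.204). Their median lay between -0.54 (mean of at least 10) and 0.91 (scaled to all reads) in other settings. The other 24 lists did not pass (adjusted p = 0.0582 to 0.976).

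The count of 19 became 3, 8 and 2 without 6h replicates 1, 2 and 3, 7, 8 and 3 without Day1 replicates 2, 3 and 4, and 64 and 41 without Day7 replicates 1 and 2. The 7 liver members became 1 to 3 without any of 6h replicates 1, 2 and 3 or any Day1 library and 11 without Day7 replicate 1 or 2. The count was 1207 when scaled to all reads, 252 when scaled to reads outside haemoglobin, 195 in DESeq2 and 9 in edgeR. With a term for Y-linked reads 2 (Ambp and Fgg) were left.

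**Figure D1:**
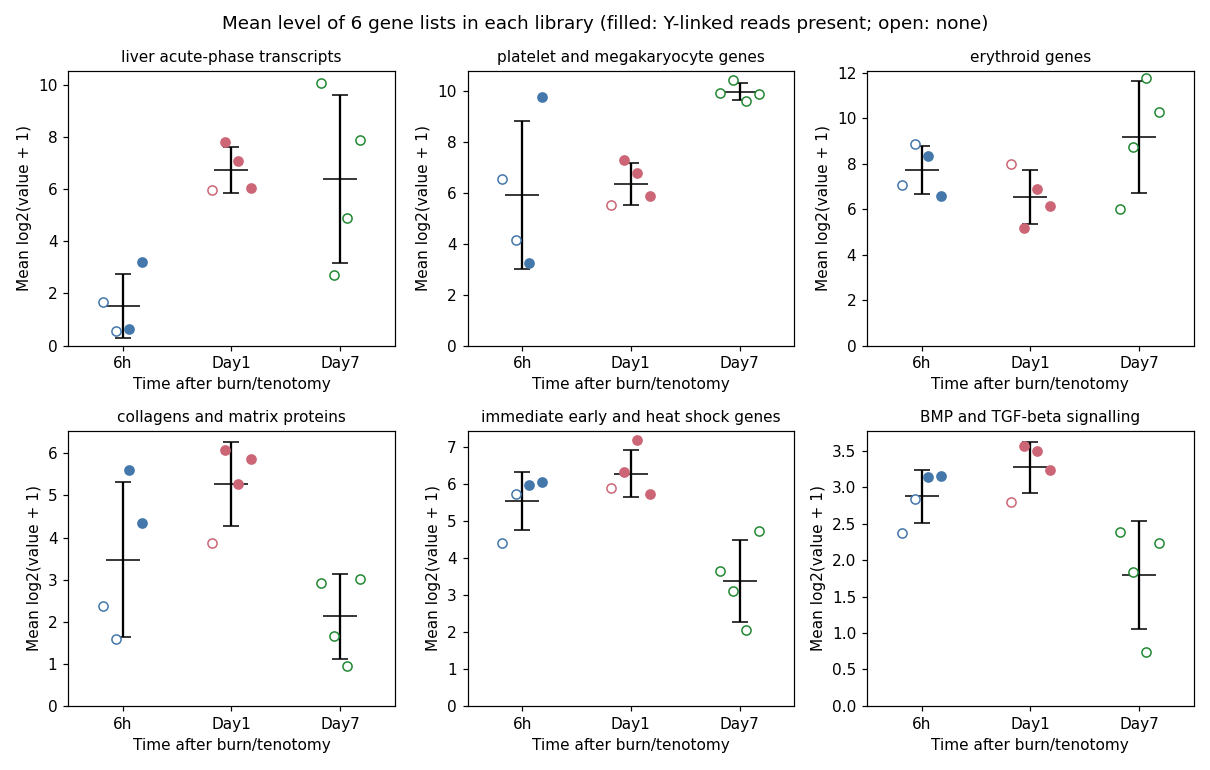
Mean log2(value + 1) over the tested members of 6 gene lists (vertical axes) in each library, by time after injury (horizontal axes). Points are libraries, filled where Y-linked reads were present, and bars are the mean and SD of 4 libraries. The liver list lies at 5.98 to 7.82 in the Day1 libraries against 0.57 to 3.20 at 6h, and the platelet list at 9.62 to 10.4 at Day7 against 5.50 to 7.30 at Day1.

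Between Day1 and Day7, 11 of 21 immediate early and heat shock genes and 8 of 19 collagens and matrix proteins fell, and 14 of 21 platelet and megakaryocyte genes rose. Id1, a target of BMP signalling, fell from 134 ± 50.04 (SD, n = 4) to 3.40 ± 3.79 (SD, n = 4), and Sparc, the matrix protein osteonectin, fell from 577 ± 486 to 17.9 ± 16.3 (SD, n = 4). Sox9, the transcription factor of early cartilage, had 635 reads at Day1 and 0 at Day7, over pooled reads at least 65.5-fold lower (61.1-fold for the means, 26.5-fold without Day7 replicate 1). Tubb1, the beta-tubulin of platelets, rose from 9.57 ± 1.63 to 417 ± 188 (SD, n = 4). In limma 648 of 11211 genes changed, 245 higher and 403 lower at Day7, and the median log2 fold change of all genes was -0.48.

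Among the genes with the largest falls were Lgals7, a galectin of stratified epithelia (log2 fold change -5.89), Ier3 (-5.68), Msln, the mesothelial protein mesothelin (-5.32), and the long non-coding RNA Meg3 (-5.27, SE 0.74, limma adjusted p = 0.00225). Immediate early and heat shock genes fell in 11 of 21 members (15 adjusted over the list alone), with Egr1 at -5.46, Hspa1a at -5.35, Fos at -5.35, Hspb1 at -5.01 and Atf3 at -4.45. That list's median was -3.01, or -3.12 with 1 member at its bound (camera adjusted p = 2.07e-08; adjusted p = 0.437 with an estimated correlation). Collagens and matrix proteins fell in 8 of 19 members (15 adjusted over the list alone), among them Sparc (-5.20), Col1a2 (-4.98), Mgp (-4.15) and Col6a1 (-4.11). Their median was -3.38 (adjusted p = 1.16e-07; adjusted p = 0.449 with an estimated correlation), or -1.08 with 0 changed under a term for Y-linked reads (adjusted p = 0.0372). The mean log2 level of this list was 5.604 and 4.342 in the 6h libraries with Y-linked reads against 2.38 and 1.59 in the others, and at Day1 5.27 to 6.08 against 3.87. Tendon genes fell in 3 of 5 members (5 adjusted over the list alone), the matrix genes Tnxb and Fmod (-3.65 for both) and Egr1, which is also on the immediate early list. The tendon median was -3.65 (adjusted p = 0.0012; adjusted p = 0.437 with an estimated correlation), and the call was lost with a term for Y-linked reads (-1.35, adjusted p = 0.0568) and with no filter (adjusted p = 0.0787).

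Of 25 BMP and TGF-beta signalling genes 4 were lower and 2 higher at Day7 (11 and 2 adjusted over the list alone), and 22 of the 25 log2 differences were negative. Id1 (-5.42, SE 0.82, limma adjusted p = 0.00373), Id3 (-5.02) and Tgfbr2, a TGF-beta receptor (-3.98), were lower, and Ltbp1, which binds latent TGF-beta, was higher (3.05). The list's median was -1.87 (adjusted p = 0.00541; adjusted p = 0.5 with an estimated correlation), and a mean of at least 10 ended the call (adjusted p = 0.0506). Circadian clock genes fell in 4 of 16 members (8 adjusted over the list alone), Per1 (-3.79), Nr1d1 (-3.65), Dbp (-3.54) and Tef (-3.46), with adjusted p = 0.00243 for the list and adjusted p = 0.449 with an estimated correlation. Glucocorticoid-responsive genes fell in 2 of 14 members (7 adjusted over the list alone; adjusted p = 0.00541; adjusted p = 0.449 with an estimated correlation), and keratinocyte genes in 2 of 7 (3 adjusted over the list alone; adjusted p = 0.0129; adjusted p = 0.437 with an estimated correlation). A term for Y-linked reads ended the circadian and glucocorticoid calls (adjusted p = 0.0598 and 0.0517). Scaling to reads outside haemoglobin or to all reads ended the keratinocyte call (adjusted p = 0.0645 and 0.0707).

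Platelet and megakaryocyte genes rose in 14 of 21 members (20 adjusted over the list alone) at Day7. Tubb1 rose by 5.21 on the log2 scale (SE 0.88, limma adjusted p = 0.00688), Gp6, a platelet collagen receptor, by 4.30 and Selp, P-selectin, by 3.44. The list's median was 3.66 (adjusted p = 2.02e-16; adjusted p = 0.437 with an estimated correlation). Scaled to reads outside haemoglobin and to all reads it was 1.83 and 1.497, against -1.92 and -1.78 over all genes, with 1 member changed in each. The other large rises were F2rl2, a thrombin receptor (5.14), Tbxas1, thromboxane synthase (4.81), Ttll11 (4.63), Bin2 (4.47), Nck2 (4.34) and reads assigned to Lars2 (4.29), whose source was not tested. Erythroid genes rose in 3 of 26 members (3 adjusted over the list alone), the transcription factor Gata1 (3.34) and the spectrins Spna1 (4.15) and Spnb1 (2.94), with a list median of 2.68 (adjusted p = 1.64e-10; adjusted p = 0.449 with an estimated correlation). Gata1 was 170.7, 149.9, 86.36 and 181.9 in Day7 replicates 1 to 4, where the mean log2 erythroid level was 5.996, 8.742, 11.76 and 10.28, so it did not follow the list there. Scaled to reads outside haemoglobin and to all reads the erythroid median was 0.95 and 0.60, against -1.92 and -1.78 over all genes, with 0 members changed in either. Mature neutrophil markers rose in 3 of 18 members (4 adjusted over the list alone), S100a8 (4.17), Trem1 (3.26) and Mxd1 (3.13), with a list median of 1.78 (adjusted p = 1.89e-05; adjusted p = 0.437 with an estimated correlation), or 0.50 with 0 changed when scaled to all reads, against -1.78 over all genes there. Mxd1 was 79.45, 158.5, 250.4 and 125 in Day7 replicates 1 to 4. The mean log2 neutrophil level was 5.353, 3.679, 3.575 and 4.073 there, so Mxd1 ran in the reverse order of its list. Proliferation genes rose in 2 of 26 members (8 higher and 1 lower adjusted over the list alone; median 1.54, adjusted p = 6.21e-05; adjusted p = 0.584 with an estimated correlation), although scaled to all reads their median was -0.11, against -1.78 over all genes, and a term for Y-linked reads ended the call (adjusted p = 0.0884). Their mean log2 level was 1.482, 2.896, 5.535 and 4.17 in Day7 replicates 1 to 4, in the order of the erythroid level. At Day1 it was 1.287 to 2.94, so only Day7 replicates 3 and 4 lay above that range. Whether the proliferation rise is separate from the erythroid rise was not tested. The other 18 lists did not pass (adjusted p = 0.067 to 0.883), the liver list among them (median -0.43, adjusted p = 0.865).

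Mesenchymal progenitor and fibroblast markers did not pass camera at Day7 against Day1 (median -1.60, adjusted p = 0.0681; adjusted p = 0.686 with an estimated correlation), although 3 of 19 members fell (8 lower and 2 higher adjusted over the list alone), Clec3b (-3.32), Pdpn (-3.06) and Mfap5 (-3.65). The abundant members Dcn, decorin (649 ± 336 at Day1, 181 ± 206 at Day7, SD, n = 4) and Cd34 (98.98 ± 57.1 and 24.5 ± 14.9, SD, n = 4) had log2 differences of -2.98 and -1.94 and did not pass in limma (adjusted p = 0.109 and 0.263). Of 5 osteogenic genes 0 changed (2 lower adjusted over the list alone), and Runx2, the transcription factor of osteoblasts, averaged 27.6 ± 26.2 at Day1 and 1.93 ± 1.73 at Day7 (SD, n = 4; limma adjusted p = 0.0642). Atf4 differed by 0.10 and Spp1, osteopontin, by -2.10, and neither passed (limma adjusted p = 0.944 and 0.434). Spp1 reached 2468 in 6h replicate 2 and 679 in Day1 replicate 4 but was at most 149 in any other library. Of 6 chondrogenic genes 1 fell (1 adjusted over the list alone), Sox9 (log2 fold change -2.81, limma adjusted p = 0.0331), whereas Sox6 (1.27) and Prg4, lubricin (-1.14), did not pass (limma adjusted p = 0.471 and 0.43). Sox6 was 1.38, 10.9, 120 and 67.5 in Day7 replicates 1 to 4, in the order of the erythroid level. Prg4 was 50.7, 4.98, 0.617 and 12.6, in the order of the hepatocyte list (7.17, 1.09, 0.957 and 5.02). At Day1 Prg4 kept that order, and Sox6 did not follow the erythroid level. Neither is a clear reading of chondrogenic cells here. Mesothelial markers, a list added after seeing the data, fell in 14 of 17 members with a median of -4.36 (camera adjusted p = 1.88e-12; adjusted p = 0.194 with an estimated correlation).

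The 648 calls became 1185 and 1154 without 6h replicates 1 and 4, 14, 3 and 20 without Day1 replicates 2, 3 and 4, and 1002, 50, 41 and 128 without Day7 replicates 1, 2, 3 and 4. Without any 1 of Day1 replicates 2, 3 and 4 or Day7 replicates 2 and 3 the changed members became 0 or 1 of the platelet list, 0 or 1 of the matrix list and 0 to 6 of the immediate early list (platelet 2 without Day1 replicate 1 or Day7 replicate 4, matrix 4 without the latter). With libraries left out singly, changed members were 0 to 17 of the erythroid list, 0 to 9 for proliferation, 1 to 9 for BMP and TGF-beta, 0 to 6 for circadian, 0 to 5 for glucocorticoid, 0 to 4 for neutrophil and 0 to 3 for keratinocyte genes, and 0 to 3 for tendon genes in the 8 of 12 runs that tested enough of them. With a term for Y-linked reads 0 genes passed in limma (1774 at an unadjusted p under 0.05, against 3266 without the term), edgeR called 1 (Lamb2, a laminin chain, chosen after its values were seen) and DESeq2 1776, and scaled to all reads 10 genes were higher and 3953 lower, 1 platelet member among the higher.

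**Figure D2:**
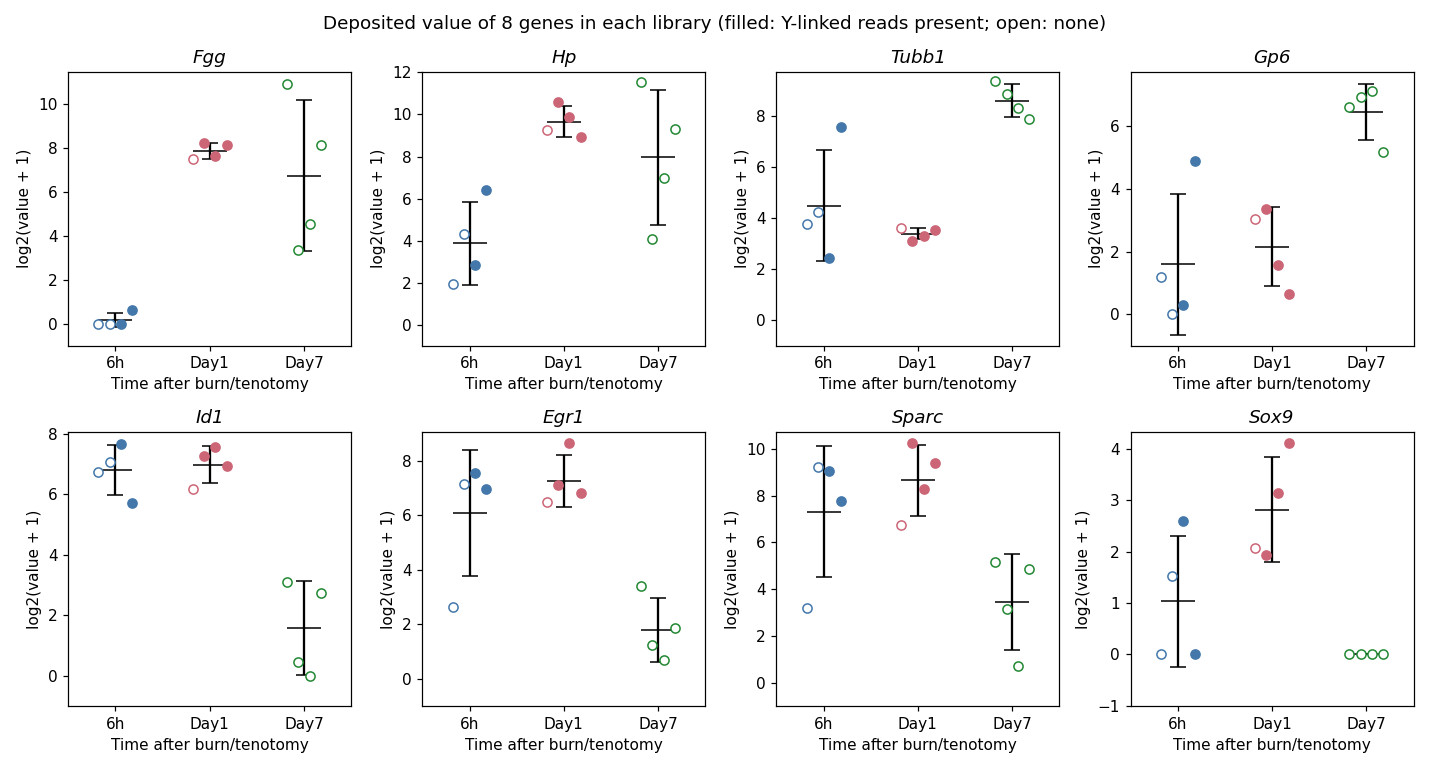
Deposited value of 8 genes as log2(value + 1) (vertical axes) in each library, by time after injury (horizontal axes). Points are libraries, filled where Y-linked reads were present, and bars are the mean and SD of 4 libraries. Fgg is at most 0.539 in the 6h libraries and at least 178 at Day1, and Id1 is at most 7.57 at Day7 and at least 52.2 at 6h and Day1.

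From 6h to Day7, 7 of 16 liver acute-phase and 7 of 21 platelet and megakaryocyte transcripts rose, and Id1 and Id3 fell. Ambp had 0 reads at 6h and 11359 at Day7, of which 10494 were in Day7 replicate 1, so over pooled reads it was at least 4474-fold higher, but 2401-fold for the means and 843-fold without that library. Apof, apolipoprotein F, and F2 were over pooled reads at least 4436-fold and 5031-fold higher, for the means 2265-fold and 2437-fold, and without that library 525-fold and 514-fold. Id1 fell from 125 ± 63.3 to 3.40 ± 3.79 (SD, n = 4). Tubb1 rose from 55.1 ± 87.3 to 417 ± 188 (SD, n = 4). In limma 99 of 11211 genes changed, 68 higher and 31 lower at Day7, with a median log2 fold change of all genes of 0.13. With 6h replicate 4 and Day7 replicate 3 exchanged between the groups, 457 genes were called.

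Liver acute-phase transcripts rose in 7 of 16 members (16 adjusted over the list alone), with Fgg at 6.56, Hpx at 6.01, Fga at 5.74 and Ttr, transthyretin, at 5.66. Their median was 5.11, or 5.70 with 3 members at their bounds (adjusted p = 9.74e-16; adjusted p = 0.437 with an estimated correlation). Spread was wide, with Fgg at 9.19, 22.2, 274 and 1896 in the 4 Day7 libraries. Scaled to all reads, 2 of the 4 Day7 libraries held more acute-phase reads than the highest 6h library, against 4 of 4 at Day1. Cyp2e1, a liver cytochrome P450, had 1 read at 6h and 15612 at Day7, a ratio of pooled reads of 18449 (95% interval of counting error 3311 to 728749), and Serpinf2, alpha-2-antiplasmin, had 1 and 6544, a ratio of 7733 (1387 to 305492). Day7 replicate 1 held 15180 and 6262 of these reads, and without it the ratios were 1264 and 825, while ratios of the means were 3155 and 9119. Apoh rose by 6.05 on the log2 scale (SE 1.00, limma adjusted p = 0.00831).

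Platelet genes rose in 7 of 21 members (21 adjusted over the list alone), among them Gp9 (5.35), Gp6 (4.86), Selp (4.24) and Tubb1 (4.11), with a median of 4.11 (adjusted p = 2.93e-18; adjusted p = 0.437 with an estimated correlation). The platelet level of 6h replicate 4 (9.74) lay with the Day7 libraries, and without it 21 of 21 members rose. Mature neutrophil markers were higher with 1 of 18 changed (7 adjusted over the list alone; adjusted p = 1.96e-06; adjusted p = 0.437 with an estimated correlation). Endothelial markers were higher with 0 of 10 changed (3 adjusted over the list alone; adjusted p = 0.0176; adjusted p = 0.449 with an estimated correlation), a call lost without 6h replicate 2 (adjusted p = 0.0804). Erythroid genes (adjusted p = 0.00379) and proliferation genes (adjusted p = 0.00811), each with 0 changed members (1 and 0 adjusted over the list alone), were higher, and both gave adjusted p = 0.728 with an estimated correlation. The erythroid call was lost without Day7 replicate 3 or 6h replicate 4 (adjusted p = 0.552 and 0.137), as was that of proliferation (adjusted p = 0.61 and 0.237). A term for Y-linked reads (adjusted p = 0.336 and 0.393), array weights (0.185 and 0.181) and a mean of at least 10 (0.15 and 0.184) ended both.

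Among changed genes chosen by the rule for groups that do not overlap, the largest falls to Day7 were Id1 (log2 fold change -5.24, SE 0.82, limma adjusted p = 0.00633), Id3 (-5.03), the signalling ligand Wnt4 (-4.70), the basal keratin Krt14 (-4.60), the epidermal gene Sbsn (-4.47), the protease Htra1 (-4.41) and Serpinh1, a collagen chaperone (-4.30). Lamb2 had 870 reads at 6h and 3 at Day7, a ratio of 245 (95% interval of counting error 83.7 to 1192). Immediate early and heat shock genes fell in 4 of 21 members (11 adjusted over the list alone), Fos (-4.36), Egr1 (-4.28), Jun (-3.75) and Hspb1 (-3.68), with adjusted p = 1.08e-10 for the list and adjusted p = 0.437 with an estimated correlation. BMP and TGF-beta genes were lower with 2 of 25 changed, Id1 and Id3 (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.000198; adjusted p = 0.437 with an estimated correlation). Collagens and matrix proteins were lower with 0 of 19 changed (2 adjusted over the list alone; median -1.28, adjusted p = 0.000144; adjusted p = 0.597 with an estimated correlation), and the median was 0.05 with a term for Y-linked reads (adjusted p = 0.348). Glucocorticoid-responsive genes (1 of 14 changed, adjusted p = 0.0018), tendon genes (1 of 5, adjusted p = 0.00936) and keratinocyte genes (1 of 7, adjusted p = 0.0093) were lower (2, 1 and 2 adjusted over the list alone), and each gave adjusted p = 0.437 with an estimated correlation. The keratinocyte call was lost without 6h replicate 1 (adjusted p = 0.0768), and the tendon call with a term for Y-linked reads (adjusted p = 0.227). Circadian genes were lower with 0 of 16 changed (0 adjusted over the list alone; adjusted p = 0.00765; adjusted p = 0.515 with an estimated correlation), a call lost with a term for Y-linked reads (adjusted p = 0.142). The other 16 lists did not pass (adjusted p = 0.0565 to 0.865).

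Of the genes named for their abundance, Dcn, Cd34, Mfap5, Sparc, Col3a1, Mgp, Sox6, Prg4, Spp1, Atf4 and Runx2 did not pass between 6h and Day7 in limma, with Sparc nearest (log2 difference -3.85, adjusted p = 0.0881). Between 6h and Day1 the same held, and Sox9, with 26 reads at 6h and 635 at Day1, had a log2 difference of 1.78 (limma adjusted p = 0.382).

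The 99 calls became 42, 3 and 695 without 6h replicates 2, 3 and 4, 41, 45 and 55 without Day1 replicates 2, 3 and 4, and 53 and 19 without Day7 replicates 1 and 4. The 7 liver members became 0 and 2 without 6h replicates 3 and 2, 2 and 1 without Day7 replicates 1 and 4, 4 without Day1 replicate 2 or 3, and 12 and 14 without 6h replicate 4 and Day7 replicate 2. The 7 platelet members became 0 without 6h replicate 2 or 3, 1 without Day7 replicate 4 and 3 without 6h replicate 1, any of Day1 replicates 2, 3 and 4 or Day7 replicate 1 or 2. Scaled to all reads 0 genes passed in limma (962 at an unadjusted p under 0.05), edgeR called 84 and DESeq2 1075, and median-of-ratios scaling gave 28 higher and 55 lower.

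Over the 3 times together, the moderated F test of limma called 286 genes. That count became 170 and 977 without 6h replicates 3 and 4, 70, 61 and 66 without Day1 replicates 2, 3 and 4, and 518, 109, 82 and 79 without Day7 replicates 1, 2, 3 and 4. Of 87 list tests 29 passed with the preset correlation, and 0 passed with an estimated correlation. For 15 lists no comparison passed. Their lowest adjusted p was 0.0565 for B cell markers, 0.0582 for plasma cell markers, 0.067 for inflammatory cytokines and NF-kB targets, 0.0681 for mesenchymal markers and 0.119 for neutrophil granule genes. It was 0.144 for dendritic cell markers and for hypoxia and glycolysis genes, 0.182 for interferon-stimulated genes, 0.293 for antigen presentation by MHC class II, 0.338 for osteogenic genes and 0.347 for monocyte and macrophage markers. It was 0.416 for NK cell and cytotoxic genes, 0.504 for chondrogenic genes, 0.627 for hematopoietic stem and progenitor genes and 0.64 for skeletal muscle genes.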

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

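The tests of the liver, matrix and platelet patterns were chosen only after the results were seen, while the counts over other splits of the libraries were planned.

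Of 320 groups of 4 values checked, 26 had 1 library far from the other 3, judged by its gap to the nearest against the range. Chance alone picks about 1 in 20 groups. That rate does not apply where 3 libraries held 0 reads, because any read in the other library then fixed the flag. These flags were Fgg, Trem1, Apoh, Cyp2e1 and Serpinf2 at 6h and Lgals7 and Sbsn at Day7.

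6h replicate 4 was sequenced deepest, with 12379041 reads against at most 6081233 in the other 6h libraries. Its mean log2 level of neutrophil granule and precursor genes was 5.70 against 2.61 to 2.81, and that of hepatocyte genes outside the acute phase was 1.56 against 0.19 to 0.42. Platelet Selp was 16.7 there against at most 0.724. It alone at 6h held reads of the neutrophil receptor Trem1 (2.52), of Fgg (0.539), of Apoh (0.360) and of Serpinf2 (0.0599). 6h replicate 1 had low Egr1 (5.23 against 124 to 189) and Jun (105 against 323 to 344). 6h replicate 2 had Lgals7 at 0 against 25.5 to 42.6, Pdpn at 0.757 against 12.1 to 17.4, and the sole Cyp2e1 read at 6h (0.379).

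Day1 replicate 4 had the highest osteogenic level of its group (5.23 against 3.52 to 3.66) and the lowest levels of mature neutrophil markers (1.72 against 2.74 to 2.94) and interferon-stimulated genes (3.41 against 3.65 to 3.71). Its F2 was 330 against 59.4 to 68.3 and its Alb 1755 against 369 to 454. Day1 replicate 1 had low Fmod (7.42 against 44.6 to 50.02) and Dbp (18.5 against 84.5 to 110). Day1 replicate 3 had the highest monocyte and macrophage level (4.00 against 3.64 to 3.70). At Day7, replicate 1 had Tgfbr2 at 4.68 against at most 0.333 and alone held reads of Lgals7 (1.03) and Sbsn (1.86). F2rl2 was 179 in replicate 4 against 247 to 257, and Dbp was 0 in replicate 3 against 7.32 to 10.1.

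The intervals of the next paragraphs are 95% intervals of a difference between groups in the mean log2 level of a list per library, by Welch or, with the term for Y-linked reads, from a linear model. Liver transcripts were higher at Day1 and Day7 than at 6h. Uneven Y-linked status is argued against as the whole cause for Day1, since with a term for Y-linked reads the interval was 1.37 to 8.61 (list median 5.07 against 5.21 without the term, median SE 1.31 against 1.23). With that term 1 member passed against 7, and 13 against 15 had an unadjusted p under 0.05. For Day1, the lowest library held 9.30 times the share of acute-phase reads among all reads of the highest 6h library. Scaling to all reads raised the median of all genes from 0.52 to 1.57, so this test could only enlarge the rise. It does not decide on the deposited scaling. The list median was above that of all genes under both, at 5.21 as deposited and 6.29 scaled to all reads. For Day7 scaling and time cannot be told apart, because the libraries spread too widely. Scaled to all reads the list median was 4.06 against 5.11, but the interval was -1.86 to 9.74 and 0 members passed, and as deposited the interval was -0.01 to 9.74 with 7. Liver cells or their RNA in the sample stay open. Hepatocyte genes outside the acute phase (0 of 22 on another list) had a median of 3.37 at Day1, and 21 of the 22 were higher. Serpinc1 and Apoc3 averaged 158 and 114 there. The interval of this list above the median of all genes was 0.78 to 3.94. It lay above 0 but reached below a limit of 1, which was set after the data were seen. The labels do not say which cells the sort removes. The rise at Day1 was not limited to the acute-phase list. Of the 19 changed genes 7 were on it. Those outside it were Ambp, F2, Kng1, Rbp4, Apof, Azgp1, Apoh, Cyp2e1, Serpinf2, Itih4, Pon1 and Itih3. Their log2 fold changes ran from 5.03 (Itih3) to 6.75 (Ambp), and they were listed after their values were seen. A response of the liver to injury, which the time groups would follow, may also contribute. It was not tested apart from liver cells or their RNA in the sample.

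Matrix genes were lower at Day7 than at Day1. Scaled to all reads the interval was -6.87 to -2.29. That scaling also lowered the median of all genes, from -0.48 to -1.78, so it could only enlarge the fall. Less the median of all genes the interval was -3.56 to -0.86 scaled to all reads and -3.60 to -0.96 as deposited. These 2 intervals argue against the deposited scaling as the whole cause. With a term for Y-linked reads the list median moved from -3.38 to -1.08 (quartiles -2.34 and -0.45), the median SE of its members went from 1.01 to 1.14 and the interval was -2.91 to 0.40. Under that term 0 members passed against 8, and 5 against 15 had an unadjusted p under 0.05. Y-linked status and time cannot be told apart for these genes, because no Day7 library and 3 of 4 Day1 libraries held Y-linked reads, so a comparison at equal status rests on 1 Day1 library. Loss of mesothelial cells or their RNA stays open, since mesothelial markers (0 of 17 on another list) fell in 14 members with an interval of -4.90 to -2.01 less the median of all genes. The mesothelial level also followed Y-linked status. It was 6.792 and 5.609 in the 6h libraries with Y-linked reads against 4.009 and 1.405 in the others, and at Day1 6.61 to 7.126 against 5.046. No interval with the Y-linked term was made for this list, so its fall cannot be told apart from that status either. Msln fell from 334 to 11.6 (log2 fold change -5.32), while Upk3b at 468 and 30.01 did not pass (limma adjusted p = 0.0512). Fewer mesenchymal cells in the blood at Day7 is an untested biological candidate explanation.

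Platelet genes were higher at Day7 than at Day1. Scaling and time cannot be told apart for the level of these genes, because scaled to all reads the interval was -0.80 to 3.73, against 2.36 to 4.84 as deposited. The list median was then 1.497 against 3.66, 1 member passed against 14, and 2 against 20 had an unadjusted p under 0.05. The all-gene median was -1.78 under that scaling and -0.48 as deposited, so the list median stayed above that of all genes in both. No interval was made for that difference. With a term for Y-linked reads the interval was 0.75 to 8.18 and the list median 4.65. As for the matrix genes, a comparison at equal status rests on 1 Day1 library, so uneven Y-linked status is not excluded. Under that term 0 members passed, as did 0 of all genes, while 21 of 21 had an unadjusted p under 0.05. Platelet carry-over through the sort may differ between days of processing, which the labels do not give, and was not tested, so it stays open beside a change of platelets with time after injury.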

How the results depend on the processing

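Scaling to all reads, the Y-linked term and leaving out the 2 libraries with fewest genes were chosen only after the data were seen, and the other tests were planned. Of 60 (mean of at least 10) to 93 (no filter) list tests with enough genes, 21 to 35 passed under each alternative fitted with limma, against 29 of 87, and no named gene that had passed changed sign in any. For other results counts follow in the order Day1 versus 6h, Day7 versus Day1, Day7 versus 6h and any time, and the cause was not tested except where fewer libraries or more genes tested account for it. The main counts were 19, 648, 99 and 286. No filter gave 0 (1768 at an unadjusted p under 0.05), 57, 13 and 16. With the pseudocount of 4 the first was 0 (1182 unadjusted), the third 5 (Id1, Id3, Maged1, Ambp and Gcet2) and the fourth 104, and with 0.25 the fourth was 154. A mean of at least 10 gave 7 for the first. Scaling to reads outside haemoglobin gave 252, 3549, 58 and 2484, and to all reads 1207, 3963, 0 (962 unadjusted) and 2960. The all-gene medians moved from 0.52, -0.48 and 0.13 to 1.44, -1.92 and -0.38 under the first and 1.57, -1.78 and -0.19 under the second. The split for Day7 versus Day1 moved from 245 higher and 403 lower to 21 and 3528, and 10 and 3953. Median-of-ratios factors gave 151 higher and 623 lower there, and 28 and 55 for Day7 versus 6h (main 68 and 31), where scaling outside haemoglobin gave 10 and 48. Array weights gave 47, 2779, 811 and 2116. Fits of 2 groups gave 82, 1901 and 7. edgeR gave 9, 1 and 84, with 10 at any time, and shared 9, 1 and 36 genes with limma, and DESeq2 gave 195, 1776, 1075 and 877. The Y-linked term gave 2 for the first, 0 (1774 unadjusted) for the second and 27 at any time. Without the 2 libraries with fewest genes the first was 4 (F2, Ambp, Fgg and Cyp11a1), the second 416 and any time 185.

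Leaving out 1 library gave 2 to 64, 3 to 1185, 3 to 695 and 61 to 977. The genes at the lowest counts were Ambp and Fgg without 6h replicate 3, Meg3, Id1 and Lamb2 without Day1 replicate 3, and Ambp, Id1 and Krt14 without 6h replicate 3. T cell markers turned from a median of -0.32 to 0.97 for Day1 versus 6h without 6h replicate 1, alone or together with Day7 replicate 3, and the lowest of the 12 leave-out medians was -0.98. Cyp11a1 was lower at Day1 in both fits. Genes named here outside the rule were chosen after their values were seen.

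With the replicate number as a block the counts were 45, 571, 156 and 308, and 33 list tests passed. The numbers do not pair the libraries, since same-numbered pairs of deviations correlated at -0.23 to 0.12, 1 of 12 above 0.1, and 1 library correlated best with its own number.

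Of the 35 splits of 8 libraries, 1 gave at least the 19 calls of Day1 versus 6h (highest other 1). Likewise 1 gave at least the 648 of Day7 versus Day1 (highest other 3). In both, that 1 was the real grouping, the smallest share that 35 splits allow. This argues against chance without excluding it, as other comparisons were tested in the same way. For Day7 versus 6h 2 splits gave at least the 99 calls, so chance cannot be excluded. The highest other called 457, with 6h replicate 4 and Day7 replicate 3 exchanged. That split points to a structure of the samples, not tested further. Of 100 splits of all 12, the real grouping among them, 2 gave at least 286 genes at any time. That share is under 0.05, but the highest other called 789, so it argues against chance without excluding it. The split with 789 may point to a structure too, not tested. At least 29 list tests passed in 35 of the 100 (highest other 42), so chance cannot be excluded for them. Depth limits low genes most, as the value of 1 read reached 0.617.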

Other observations

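In this part the tests of the mesothelial and hepatocyte lists were chosen after seeing the data. Mesothelial markers, genes of the lining of body cavities, were 17 in number among tested genes. From 6h to Day1 their median log2 difference was 1.94 with 0 changed members (camera adjusted p = 4.88e-05; adjusted p = 0.287 with an estimated correlation). At Day7 against Day1 the median was -4.36 with 14 lower (camera adjusted p = 1.88e-12; adjusted p = 0.194 with an estimated correlation), and at Day7 against 6h it was -2.38 with 0 changed members (camera adjusted p = 2.78e-09; adjusted p = 0.194 with an estimated correlation). Their mean log2 level was 1.40 in 6h replicate 2, against 4.01, 6.79 and 5.61 in the other 6h libraries, 5.05 to 7.13 at Day1 and 0.23 to 3.42 at Day7. Hepatocyte genes outside the acute phase had a median difference of 3.07 at Day7 against 6h with 1 of 22 higher (9 adjusted over the list alone; camera adjusted p = 2.78e-09; adjusted p = 0.198 with an estimated correlation), and of -0.32 at Day7 against Day1 with 0 changed (camera adjusted p = 0.82).

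Some immune cell marker lists varied widely within the 6h and Day7 groups. The MHC class II list had a mean log2 level of 6.70 in 6h replicate 1 and 1.65 in 6h replicate 2. B cell markers were at 0.72 in Day7 replicate 3 and 3.62 to 4.29 in the other Day7 libraries. Reads assigned to Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, reached 25128 in Day7 replicate 3 and 6562 in 6h replicate 2 and were between 181 and 351 in the Day1 libraries. Whether these reads came from the mRNA of that gene was not tested, and no mitochondrially encoded gene was in the table to compare. Xist, the transcript of the inactive X chromosome, had 736 reads in Day1 replicate 1 and 227, 41, 9 and 72 in the Day7 libraries. Day1 replicate 2 held 18 Xist reads together with 603 Y-linked reads. Cyp11a1, the first enzyme of steroid synthesis, averaged 347 ± 555 (SD, n = 4) at 6h and 0.402 ± 0.803 (SD, n = 4) at Day1, a difference that did not pass in limma (log2 difference -5.75, adjusted p = 0.0799).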
